A study of Mus musculus with 23 samples.

How the data were processed

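Ovary RNA of female mice from 3 inbred strains was profiled by RNA sequencing on 2 diets. C57BL/6J is the common laboratory strain, CAST/EiJ is derived from wild Mus musculus castaneus, and NZO/HlLtJ is a polygenic model of obesity and diabetes. Per the labels, mice received a control diet with 10% fat or a high fat, high sugar diet with 44% fat, both with fiber, from 6 weeks of age, and tissue was taken at 15 weeks. The submitters' extract protocol describes polyA selection, a KAPA mRNA library kit and sequencing as 100 bp read pairs to a target of 30 M pairs.

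The deposited table of expected counts, which the authors estimated per gene, held 24716 genes in 23 libraries. The values were read as estimated counts because 27.4% of them were not whole numbers and the library totals differed. Every gene in the table was above 0 in at least 12 libraries, and 342 genes were above 0 in exactly 12. A filter on detection before deposit would give this, but no source states one. The aligner, counting tool and annotation release are not given in the sources used. The submitters' notes name the genome build GRCm38 and DESeq2, with no versions. The authors also deposited a table of variance-stabilised values on a log2 scale, with a floor of 6.719 in every library, which served only as an alternative. Gene coordinates were taken from the authors' deposited annotation, in megabases, and written as whole positions. Of the genes in the table, 24557 matched the GENCODE M21 annotation by identifier, and 20156 had the same start and end there; its gene types were used to mark pseudogenes.

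Expected counts were rounded to whole numbers. Library totals ranged from 31.94 to 45.85 M counts. The 33 pairs of libraries within groups differed by 11.74 to 209.3 chi-square units per degree of freedom, so no pair looked like 1 library deposited more than once. The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries, which may be partly technical. Groups held 3 libraries (C57BL/6J on 10% fat) or 4 libraries (the other groups), numbered in deposit order, which pairs nothing.

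Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 20189 genes, or 81.7%. Counts were scaled with trimmed mean of M values factors and fitted with edgeR's robust quasi-likelihood model, with 6 group means over all 23 libraries. From it 11 comparisons were drawn, namely the diet effect in each strain and averaged over strains, the strain-by-diet terms, and the strain differences averaged over diets. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. The common biological coefficient of variation was 0.268. Levels are counts-per-million (CPM) computed from the scaled libraries and are given as mean ± SD. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

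Gene lists of cell type markers and pathways were tested with limma's camera on voom values, with a preset correlation of 0.01 and adjustment over the 34 lists with at least 4 tested genes. Lists for brown adipocytes and skeletal muscle had 2 tested genes each and were not tested. An estimated correlation was the alternative. Members past the threshold were counted over all genes and also adjusted over the list alone. A list score of a library is the median over members of log2 CPM relative to the median library, with a prior count of 2.

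The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. In diet and strain comparisons the rule takes up to 10 genes per direction with the largest fold change among those past the threshold, with a mean of at least 5 CPM in the higher group, a symbol that is not a clone or predicted-gene name, no pseudogene type, and no overlap between libraries of the sides compared. For diet averaged over strains, the effect had to have the same sign in each strain. In strain-by-diet comparisons it takes the 10 smallest p past the threshold. Where fewer than 5 passed, the 5 genes with the smallest p are given as values. Some genes that the rule selects are not reported. Up to 4 members are named from each list described, and the strain allele list is given in full. Which lists are described in which comparison was chosen after their tests were seen.

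Alternatives were DESeq2, relative log expression scaling, no count filter, only the groups compared, the series of the library identifier as a term, 2 surrogate variables, limma with library quality weights, limma on the authors' variance-stabilised values, and each library left out in turn. The fit without both libraries with the most oviduct RNA was added after the data were seen. The identifier series (76, 82 and 90) may mark batches, though no label says so. NZO/HlLtJ on 44% fat had no library in series 82, and C57BL/6J on 10% fat and NZO/HlLtJ on 10% fat had none in series 90.

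The procedure was tested on simulated counts for diet in CAST/EiJ, over 19897 genes with 200 changed. It recovered 46% of genes changed 1.5-fold, 74% at 2-fold, 96% at 4-fold and 98% at 8-fold. In all, edgeR recovered 157 and called 7 unchanged genes, DESeq2 167 and 32, and limma with library weights 157 and 10. These rates need not hold for real libraries: wrong diet labels in CAST/EiJ gave up to 196 genes. Genes with a nearly identical copy or an overlapping partner are uncertain, as reads could split between them, and counting by strand is not stated. A gene with no counts on 1 side is given as a lower bound against a floor of 3 counts over that side, and one with 1 to 3 counts as a ratio with its 95% exact binomial interval; both cover counting error only.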

Results

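Gene expression was measured in 23 ovary libraries of 3 inbred strains on 2 diets, to ask how strain and diet act, alone and together. The 44% fat diet was also high in sugar, so fat and sugar cannot be told apart. Cycle stage was not labelled and may differ between diets. C57BL/6J had 3 libraries on 10% fat and 4 on 44% fat, and CAST/EiJ and NZO/HlLtJ 4 on each diet. Library totals averaged 39.02 ± 4.126 M estimated counts (SD, n = 23), and 20189 of the 24716 genes listed were tested. Positions are on genome build GRCm38.

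Libraries were ordered mainly by strain. The first component, with 56.6% of the variance of the 1000 most variable genes, parted the CAST/EiJ libraries (scores of -77.47 to -63.36) from the others (29.96 to 40.63). The second component, with 17.1%, parted C57BL/6J (25.09 to 47) from NZO/HlLtJ (-34.22 to -28.43). RNA of neighbouring tissue varied between libraries. Oviduct epithelium markers, of the ciliated and secretory cells of the tube beside the ovary, had a median score of 6.37 log2 units above the median library in CAST/EiJ 10% fat replicate 2 and 4.07 in C57BL/6J 44% fat replicate 1. The other 21 libraries lay between -0.83 and 1.78. White adipocyte markers scored 6.59 in CAST/EiJ 10% fat replicate 2, 4.53 and 3.72 in CAST/EiJ 44% fat replicates 1 and 2, and 3.41 in C57BL/6J 44% fat replicate 1. A fit without both libraries highest in oviduct RNA was added.

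**Figure D1:**
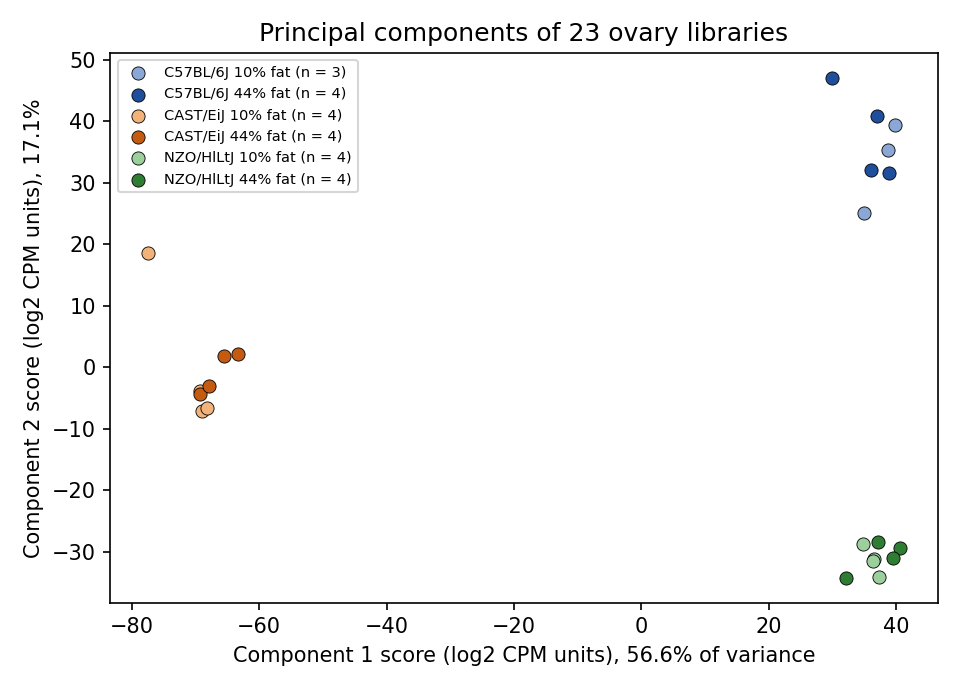
Scores of the 23 ovary libraries on the first component (horizontal, 56.6% of the variance) and the second (vertical, 17.1%) of the 1000 most variable genes, in log2 CPM units, with 1 point per library coloured by strain and diet. CAST/EiJ libraries lie between -77.47 and -63.36 on the first component and all others between 29.96 and 40.63.

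In CAST/EiJ, markers of macrophages and genes of steroid synthesis were higher as groups on 44% fat. In camera the adjusted p were 2.03e-16 for macrophages and 3.33e-08 for steroidogenesis, and the adjusted p were 0.0669 and 0.00234 with an estimated correlation. Of 13 macrophage markers 7 rose and 6 did not pass, and 11 rose adjusted over the list alone. C1qa, C1qb and C1qc, the chains of complement C1q made mainly by tissue macrophages, rose 2.03-fold, 2.06-fold and 2.01-fold, and the mannose receptor Mrc1 rose 1.76-fold. C1qb went from 26.6 ± 4.13 to 54.7 ± 18.5 CPM (SD, n = 4 each), with an edgeR adjusted p of 0.0187. Of 16 steroidogenesis genes 2 rose and 14 did not pass, and 5 rose adjusted over the list alone. The 2 were Cyp11a1, the enzyme that makes pregnenolone from cholesterol, at 1510 ± 448 and 3850 ± 739 CPM, and Fdx1, the ferredoxin that passes electrons to it, at 271 ± 67.7 and 516 ± 107 CPM (edgeR adjusted p of 0.0219 and 0.0397).

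No other list in this comparison than steroidogenesis passed with an estimated correlation. The calls of C1qa, C1qb, C1qc, Mrc1 and Cyp11a1 were lost without CAST/EiJ 44% fat replicate 2, with edgeR adjusted p of 0.0646, 0.0578, 0.0578, 0.0832 and 0.0585. That of Cyp11a1 was lost also without CAST/EiJ 44% fat replicate 3 (0.067) and with the identifier series as a term (0.0538), and that of C1qa without both libraries with the most oviduct RNA (0.0551). The call of Fdx1 was lost in 11 of its 28 alternative fits, with adjusted p of up to 0.13, reached without CAST/EiJ 44% fat replicate 2.

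**Figure D2:**
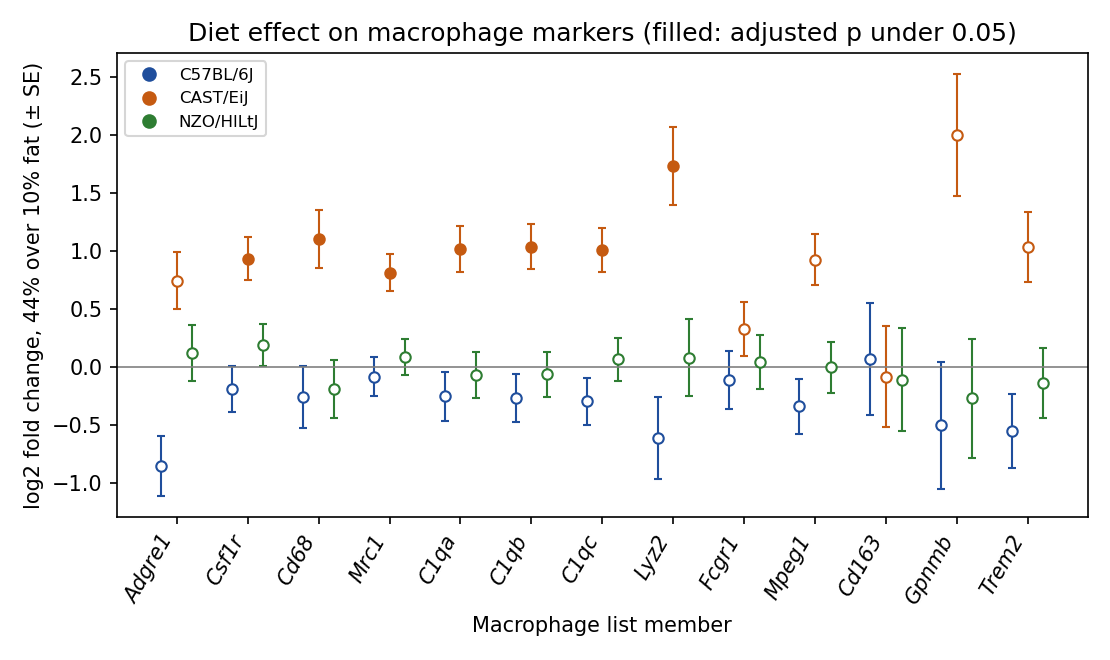
Diet effect (vertical, log2 fold change of 44% over 10% fat ± SE) on the 13 macrophage markers (horizontal) in each strain, with filled points at an adjusted p under 0.05. In CAST/EiJ 7 markers are filled and 12 of 13 lie above 0, while in C57BL/6J 1 of 13 lies above 0 and in neither other strain is any filled.

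Markers of luteal cells, the steroid-making cells formed after ovulation, were also higher as a group in CAST/EiJ on 44% fat, though 0 of 8 passed the test in edgeR. The camera adjusted p was 1.9e-05 for the list, or an adjusted p of 0.0669 with an estimated correlation. Adjusted over the list alone, 5 rose. The prostaglandin receptor Ptgfr was at 15.3 ± 11.6 CPM on 10% fat and 111 ± 76.1 on 44% fat, Akr1c18, which breaks down progesterone, at 31.7 ± 41.6 and 298 ± 231, and the lipoprotein receptor Scarb1 at 392 ± 72.2 and 732 ± 204 (n = 4 each; edgeR adjusted p of 0.0936, 0.138 and 0.0792). DESeq2 called Ptgfr, Akr1c18, Scarb1 and Sfrp4, a Wnt inhibitor, with adjusted p of 0.00793, 0.0218, 0.0103 and 0.0217. Sfrp4 passed also in edgeR without CAST/EiJ 10% fat replicate 2 (0.0384) and without both libraries with the most oviduct RNA (0.0444). The luteal score was -0.998 ± 0.385 on 10% fat and 0.00715 ± 0.119 on 44% fat, without overlap between the diets. The log2 fold change of Akr1c18 moved from 3.23 to 4.63 and that of Ptgfr from 2.85 to 3.46 without CAST/EiJ 10% fat replicate 3, and Akr1c18 to 2.55 without CAST/EiJ 44% fat replicate 1.

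**Figure D3:**
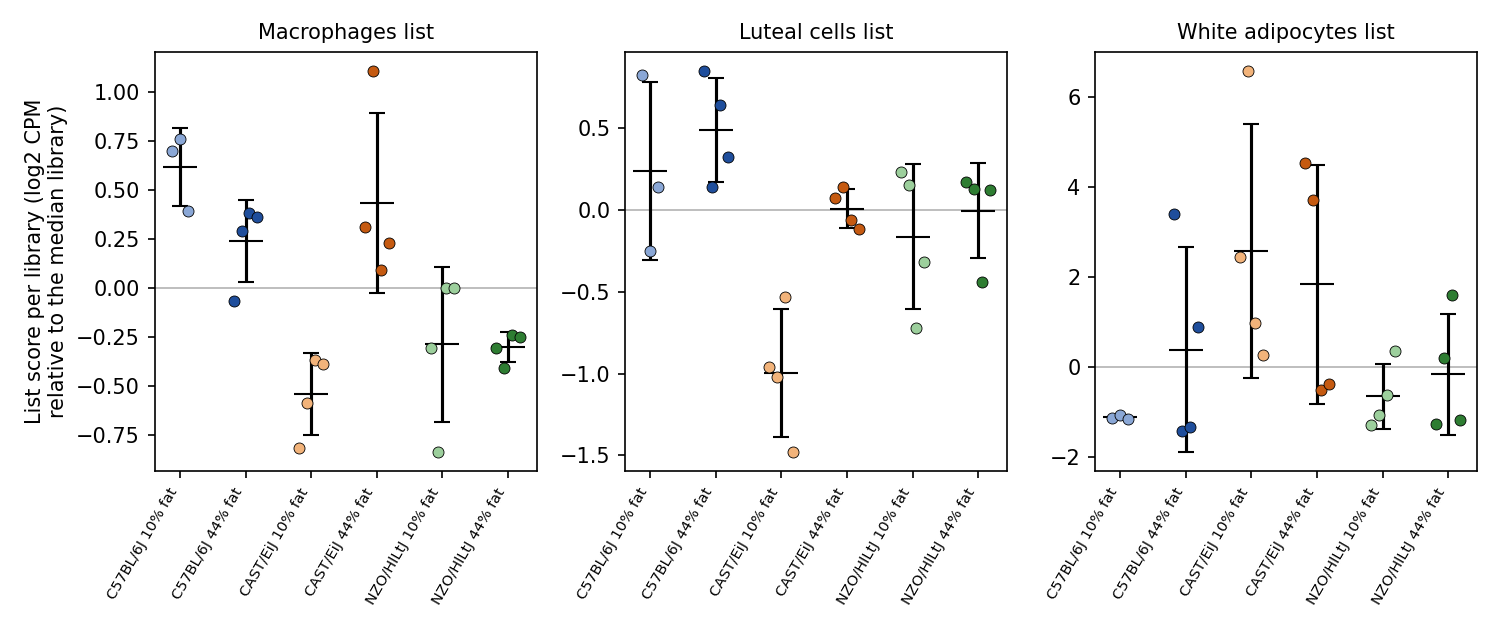
Scores of the macrophage, luteal cell and white adipocyte lists (vertical, log2 CPM relative to the median library) by group (horizontal), with 1 point per library and bars for the mean ± SD. Luteal scores of CAST/EiJ lie between -1.48 and -0.53 on 10% fat and between -0.12 and 0.14 on 44% fat, and the white adipocyte score reaches 6.59 in CAST/EiJ 10% fat replicate 2.

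Fatty acid oxidation and extracellular matrix lists were higher in CAST/EiJ on 44% fat. In camera the adjusted p were 3.55e-06 and 1.08e-07, and the adjusted p were 0.0792 and 0.313 with an estimated correlation. The matrix score was 0.39 in CAST/EiJ 44% fat replicate 1 and 0 to 0.05 in the other 3 libraries of its group, with a mean of -0.272 on 10% fat. Acadm, the medium-chain acyl-CoA dehydrogenase of mitochondria, rose 1.36-fold, from 115 ± 10 to 157 ± 8.01 CPM (n = 4 each; edgeR adjusted p of 0.0034), and was the single member of 20 that passed, over all genes and adjusted over the list alone. The long-chain enzymes Acadvl and Acadl stood at 1.16-fold each, with adjusted p of 0.174 and 0.207. Of 23 matrix genes 0 passed in edgeR and 5 rose adjusted over the list alone, with the matrix protease Mmp2 at 238 ± 37.9 and 457 ± 148 CPM (adjusted p of 0.0585) and the collagen Col6a1 at 409 ± 85.6 and 587 ± 41.5 CPM (0.114). DESeq2 called Mmp2 and Col6a1, with adjusted p of 0.00406 and 0.0372, and Mmp2 passed also in edgeR without C57BL/6J 10% fat replicate 2 (0.0431) or CAST/EiJ 44% fat replicate 4 (0.0385).

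Genes of the ovulatory response to luteinizing hormone were lower in CAST/EiJ on 44% fat, and this rested on 1 library. The camera adjusted p was 0.0253, or an adjusted p of 0.948 with an estimated correlation. Ptgs2, the inducible prostaglandin synthase of the ovulating follicle, was at 4.48 ± 7.97 CPM on 10% fat and 0.201 ± 0.0683 on 44% fat, and the hyaluronan-binding protein Tnfaip6 at 3.47 ± 6.05 and 0.478 ± 0.272 (n = 4 each). Of 12 genes 0 passed in edgeR, where Ptgs2 had an adjusted p of 0.0745 and Tnfaip6 0.14, and 3 fell adjusted over the list alone; DESeq2 gave 0.00058 and 0.0174. Without CAST/EiJ 10% fat replicate 2, the library with the highest oviduct and adipocyte scores, the list turned to the opposite direction with a camera adjusted p of 0.98 (0.99 without both libraries with the most oviduct RNA). In both fits the log2 fold change of Tnfaip6 turned from -2.84 to 0.11 and that of Ptgs2 moved from -4.45 to -1.29. Ptgs2 passed in edgeR without CAST/EiJ 10% fat replicate 1 (0.0318) or replicate 4 (0.0334).

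Over all genes, 126 differed between diets in CAST/EiJ in edgeR, 106 higher and 20 lower on 44% fat. Among the largest increases were those of Wnt10b, a secreted Wnt ligand, at 29.3-fold, Abcb1b, a drug efflux pump, at 19.8-fold, the exchange factor Plekhg4 at 18.4-fold and the crystallin Crybb1 at 12.6-fold. The neurotransmitter receptor partner Shisa7 rose 7.97-fold. Cyp4f18 (ENSMUSG00000003484, chromosome 8, 71988482 to 72009626) and Cyp4f14 (chromosome 17, 32905071 to 32917342), cytochromes P450 of the family that hydroxylates leukotrienes, rose 5.8-fold and 3.31-fold. Cyp4f18 went from 7.53 ± 2.63 to 43.6 ± 14.5 CPM, with an edgeR adjusted p of 0.0034. The lysosomal protease Lgmn rose 3.42-fold, from 88.4 ± 15.7 to 302 ± 127 CPM, and the lysozymes Lyz2 and Lyz1 of macrophages rose 3.33-fold and 3.84-fold, where each is uncertain because the 2 genes are nearly identical neighbours on chromosome 10. Adam11, a protease-family protein, fell 2.78-fold, from 50.8 ± 11.5 to 18.3 ± 8.07 CPM, the motor adaptor Hook1 1.6-fold and the calcineurin regulator Rcan3 1.29-fold. Calb1, a calcium-binding protein, was at 18.7 ± 34.3 CPM on 10% fat and 0.846 ± 0.0646 on 44% fat. By the rule that chose these genes, no library of either diet overlapped with those of the other. Fold changes moved by over 1.5 times without CAST/EiJ 44% fat replicate 3 for Wnt10b (log2 from 4.87 to 4.24), Abcb1b (4.3 to 3.53) and Shisa7 (2.99 to 1.97), and without CAST/EiJ 44% fat replicate 1 for Plekhg4 (4.2 to 2.81) and Crybb1 (3.66 to 2.35). Without CAST/EiJ 10% fat replicate 3 Wnt10b was at 5.9, and without CAST/EiJ 10% fat replicate 2 or both libraries with the most oviduct RNA Calb1 moved from -4.46 to -0.84. With 2 surrogate variables Wnt10b was at 3.86, Abcb1b at 3.66 and Calb1 at -1, and with the identifier series Plekhg4 was at 3.61.

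The calls of Shisa7, Cyp4f18 and Cyp4f14 held in the 28 alternative fits for single genes, with edgeR or DESeq2 adjusted p of up to 0.0444, 0.0219 and 0.0444. These fits did not include edgeR on the CAST/EiJ libraries alone, which called 0 genes, so that each call was lost there. Calb1 was lost in 22 of 27, Plekhg4 in 20, Rcan3 in 16 and Lyz1 in 13 of 28, with the highest adjusted p of 0.257 for Calb1 without CAST/EiJ 10% fat replicate 2, 0.13 for Plekhg4 without CAST/EiJ 44% fat replicate 1, 0.13 for Rcan3 without CAST/EiJ 44% fat replicate 3 and 0.16 for Lyz1 without CAST/EiJ 44% fat replicate 2. Without CAST/EiJ 10% fat replicate 2, Wnt10b (0.0653) and Lyz2 (0.0597) were lost, without CAST/EiJ 44% fat replicate 3 Wnt10b (0.0534) and Abcb1b (0.0516), without CAST/EiJ 44% fat replicate 1 Lgmn (0.0518), and without CAST/EiJ 44% fat replicate 2 Lyz2 (0.0832), Adam11 (0.063) and Hook1 (0.0865). With 2 surrogate variables Wnt10b (0.0981), Abcb1b (0.0574), Crybb1 (0.0525) and Hook1 (0.0523) were lost, with the identifier series Wnt10b (0.0526) and Adam11 (0.0525), and without both libraries with the most oviduct RNA Wnt10b (0.0776), Abcb1b (0.0598), Lgmn (0.0502) and Hook1 (0.0518).

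The count of 126 moved by over 1.5 times without 7 libraries, to 28 without CAST/EiJ 44% fat replicate 2, 221 and 214 without CAST/EiJ 10% fat replicates 1 and 4, 79 and 78 without NZO/HlLtJ 44% fat replicates 1 and 2, and 82 and 83 without C57BL/6J 44% fat replicates 2 and 3. DESeq2 gave 596 genes, 339 higher and 257 lower, among them 124 of the 126. The identifier series gave 66 and limma with library weights 240, sharing 65 and 96 of the 126, limma on the authors' variance-stabilised values 80, sharing 75, and edgeR on the CAST/EiJ libraries alone 0.

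In C57BL/6J, 0 genes passed between diets in edgeR, with 1783 at an unadjusted p under 0.05. DESeq2 gave 70, 21 higher and 49 lower, and limma with library weights 832. The 5 genes with the smallest p were lower on 44% fat in value. Lhpp, a histidine phosphatase, was at 34.2 ± 8.77 CPM (n = 3) on 10% fat and 17.4 ± 0.406 (n = 4) on 44% fat, with an edgeR adjusted p of 0.118. Tmem35, the exchange factor Net1, the lymphocyte receptor Cd244 and the glutaredoxin Glrx stood at 1.89, 1.54, 6.37 and 1.55 times lower, with an adjusted p of 0.327 each. DESeq2 called all 5, with adjusted p of 1.69e-05 for Lhpp, 0.00296 for Tmem35, 0.00944 for Net1, 0.00438 for Cd244 and 0.01 for Glrx. Without C57BL/6J 10% fat replicate 2, edgeR called 326 genes, among them these 5 with adjusted p of 0.00128, 0.00241, 0.0116, 0.0062 and 0.0103.

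Immediate early genes, which respond within minutes to stimuli, and genes of the unfolded protein response were higher as groups in C57BL/6J on 44% fat, and macrophage markers were lower. Camera adjusted p were 2e-05, 0.000274 and 0.00127 in this order, and the adjusted p were 0.596, 0.668 and 0.706 with an estimated correlation. Of 17 immediate early genes 0 passed in edgeR, over all genes or adjusted over the list alone, and 16 had a positive fold change, such as Fos at 6.78 ± 4.86 and 15.5 ± 2.46 CPM and Klf4 at 7.66 ± 1.5 and 12.7 ± 2.74 (adjusted p of 0.503 and 0.396). Of 20 unfolded protein response genes 0 passed, over all genes or adjusted over the list alone, and 19 were positive, with the chaperone Hspa5 at 972 ± 193 and 1390 ± 195 CPM (0.396), which passed without C57BL/6J 10% fat replicate 2 (0.0417). Of 13 macrophage markers 0 passed over all genes and 1 fell adjusted over the list alone, and the macrophage surface protein Adgre1 was at 43.3 ± 25.7 and 24 ± 4.1 CPM (0.396). Without both libraries with the most oviduct RNA the macrophage list was lost, with a camera adjusted p of 0.109. Without C57BL/6J 10% fat replicate 2, Fos moved from 1.19 to 1.96 and Adgre1 from -0.85 to -0.26 on the log2 scale. The lists of oocytes, theca and granulosa cells were also higher in camera (adjusted p of 2e-05, 0.00218 and 0.0259, and adjusted p of 0.706, 0.596 and 0.714 with an estimated correlation), with 0 genes past over all genes and 0, 3 and 0 past adjusted over the list alone. The granulosa list was lost also with the identifier series (0.0997). The 10% fat libraries stood apart, with granulosa scores of -0.81, 0.6 and -0.63 and oocyte scores of -1.61, 0.05 and -0.29 in replicates 1, 2 and 3, against 0.0493 ± 0.0463 and -0.176 ± 0.138 (n = 4) on 44% fat.

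Oviduct epithelium markers were higher in C57BL/6J on 44% fat, chiefly in the replicate described above. The camera adjusted p was 0.00476, or an adjusted p of 0.706 with an estimated correlation. Of 10 markers 0 passed in edgeR and 7 rose adjusted over the list alone; the ciliary motor gene Dnah5 was at 0.149 ± 0.131 and 8.65 ± 14.1 CPM and the ciliogenesis factor Foxj1 at 0.0948 ± 0.0304 and 6.39 ± 10.6 (adjusted p of 0.327 and 0.453). DESeq2 called Dnah5 (0.000325) and the transcription factor Pax8 of the tubal epithelium (0.0303). Without C57BL/6J 44% fat replicate 1, or both libraries with the most oviduct RNA, Dnah5 moved from 5.9 to 3.51 and Foxj1 from 6.01 to 3.48 on the log2 scale, and without C57BL/6J 10% fat replicate 1 Dnah5 was at 5.29.

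In NZO/HlLtJ, 0 genes passed between diets in edgeR, with 710 at an unadjusted p under 0.05, while DESeq2 gave 4 and limma with library weights 2. Eftud1, a GTPase of ribosome assembly, had the smallest p, at 34.6 ± 2.74 CPM on 10% fat and 43.6 ± 2.69 on 44% fat (n = 4 each), with adjusted p of 0.524 in edgeR and 0.000189 in DESeq2. Next in p were the eotaxin Ccl11, Fam78b and the lectin Mlec of the endoplasmic reticulum, at 5.5, 2.08 and 1.18 times lower, with an edgeR adjusted p of 1 each. Without NZO/HlLtJ 44% fat replicate 3, 1 gene passed.

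Genes of the unfolded protein response, of the extracellular matrix and of cytokine signalling were lower as groups in NZO/HlLtJ on 44% fat. Camera adjusted p were 2.37e-09, 4.87e-05 and 0.0316, and the adjusted p were 0.376, 0.791 and 0.988 with an estimated correlation. Of 20 unfolded protein response genes 0 passed in edgeR, over all genes or adjusted over the list alone, and 2 had a positive fold change; the protein disulfide isomerase Pdia4 was at 420 ± 102 and 257 ± 15.4 CPM and the chaperone partner Sdf2l1 at 23.5 ± 4.95 and 15.9 ± 2.21. Of 23 matrix genes 0 passed, over all genes or adjusted over the list alone, and 3 were positive, with the inhibitor of matrix proteases Timp1 at 76.2 ± 58.8 and 21.8 ± 1.34 CPM. Of 18 cytokine genes 0 passed over all genes and 1 fell adjusted over the list alone, and the monocyte attractants Ccl2 and Ccl7 were at 5.23 ± 5.62 and 0.885 ± 0.176 CPM and at 3.07 ± 3 and 0.314 ± 0.12 CPM. Each of these 5 genes had an edgeR adjusted p of 1. The cytokine list was lost with the identifier series as a term, with a camera adjusted p of 0.176. Ccl2 moved in log2 fold change from -2.56 to -1.61 and Ccl7 from -3.26 to -2.49 without NZO/HlLtJ 10% fat replicate 4, and Timp1 from -1.81 to -1.12 without NZO/HlLtJ 10% fat replicate 3 and to -1.22 with the identifier series.

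Averaged over the 3 strains, 0 genes passed for diet in edgeR, with 1190 at an unadjusted p under 0.05, while DESeq2 gave 18 and limma with library weights 1. Smallest in p was Clca3a1, a chloride channel accessory protein, 1.3-fold in value on 44% fat (edgeR adjusted p of 0.382). The IGF binding protein protease Pappa2 was 12.9 times lower (0.462) and high in only some 10% fat libraries, given below. Next were the potassium channel Kcnt1 and Adam11, 1.43 and 1.76 times lower, and the fibulin Fbln7, 1.42-fold (0.507 each). DESeq2 called all 5, with adjusted p of 0.000681, 2.22e-05, 0.00628, 0.0068 and 0.022. Without C57BL/6J 10% fat replicate 2, edgeR called 7 genes, among them Clca3a1 (0.042), Pappa2 (0.042) and Adam11 (0.0462). On the log2 scale Pappa2 moved from -3.68 to -2.68 without NZO/HlLtJ 10% fat replicate 3 and to -2.37 with 2 surrogate variables.

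Genes of cholesterol synthesis and luteal markers were higher as groups on 44% fat over the strains, and genes of hypoxia and glycolysis were lower. Camera adjusted p were 1.19e-05, 3.93e-05 and 3.23e-05, and the adjusted p were 0.483, 0.222 and 0.228 with an estimated correlation. The cholesterol score went from 0.131 to 0.116 in NZO/HlLtJ and the hypoxia score from 0.0653 to 0.0687 in CAST/EiJ. The luteal score went from -0.998 to 0.00715 in CAST/EiJ, 0.237 to 0.484 in C57BL/6J and -0.165 to -0.00492 in NZO/HlLtJ. Of 24 cholesterol genes 0 passed in edgeR and 1 rose adjusted over the list alone; squalene synthase Fdft1 stood at 1.28-fold. Of 8 luteal markers 0 passed and 3 rose adjusted over the list alone, with the receptor of luteinizing hormone Lhcgr at 1.77-fold and Scarb1 at 1.41-fold. Of 16 hypoxia and glycolysis genes 0 passed and 2 fell adjusted over the list alone, with the kinase Pdk1, which holds pyruvate back from mitochondria, 1.22 times lower (edgeR adjusted p of 0.507, and 0.0409 in DESeq2) and phosphoglycerate kinase Pgk1 1.29 times lower. Of 12 ovulatory genes 0 passed and 4 fell adjusted over the list alone, with Adamts1, a protease of the ovulating follicle, 2.62 times lower in value. This list had a camera adjusted p of 0.0146, or an adjusted p of 0.576 with an estimated correlation, and the call was lost without CAST/EiJ 10% fat replicate 2 (0.273), without both libraries with the most oviduct RNA (0.231) and with the identifier series (0.0778). Adamts1 moved from -1.39 on the log2 scale to -0.63 and -0.65 in the first 2 of these fits, and to -0.47 with 2 surrogate variables.

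Strain differences in diet response were tested with interaction terms. The smallest p belonged to Tbx3, a T-box transcription factor, the mitochondrial chaperone Dnajc15, Acadm, the integrin activator Fermt3 of blood cells and Cyp4f14. They were followed by Tmem86a, Tst, an enzyme that detoxifies cyanide, Unc93b1, which guides toll-like receptors to endosomes, and the lysosomal enzymes Lipa and Ctsa. Each had an edgeR adjusted p of 0.02. Lipa, the acid lipase, was at 138 ± 31.8 CPM (n = 3) on 10% fat and 89 ± 15.4 on 44% fat in C57BL/6J, 88.9 ± 13.4 and 149 ± 16.9 in CAST/EiJ, and 86.1 ± 12.9 and 74.5 ± 2.8 in NZO/HlLtJ (n = 4 each). In all 23 genes passed, and 544 in DESeq2, which held all 23, and 998 in limma with library weights.

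The count was 320 without C57BL/6J 10% fat replicate 2, 76 and 55 without NZO/HlLtJ 10% fat replicates 2 and 3, 0 without CAST/EiJ 10% fat replicate 1, and 11 without C57BL/6J 44% fat replicate 1 or 3. It was 12 without C57BL/6J 10% fat replicate 1 or NZO/HlLtJ 44% fat replicate 1 or 3, 13 without C57BL/6J 44% fat replicate 2, NZO/HlLtJ 10% fat replicate 1 or NZO/HlLtJ 44% fat replicate 2 or 4, 14 without NZO/HlLtJ 10% fat replicate 4, and 15 without CAST/EiJ 10% fat replicate 3. It was 2 with the identifier series, 3 with 2 surrogate variables and 0 without both libraries with the most oviduct RNA. Each of the 10 genes named was lost without CAST/EiJ 10% fat replicate 1 (adjusted p of 0.0648), with 2 surrogate variables (0.0533 to 0.0859) and without both libraries with the most oviduct RNA (0.0552 to 0.0754). All but Tbx3 and Dnajc15 were lost with the identifier series (0.0584), and Ctsa without CAST/EiJ 44% fat replicate 3 (0.0514).

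Between CAST/EiJ and C57BL/6J, the response of macrophage markers differed as a group. The camera adjusted p was 3.14e-13, or an adjusted p of 0.154 with an estimated correlation. Of 13 markers 5 responded more upward in CAST/EiJ and 8 did not pass, and 11 did adjusted over the list alone. The ratio of the 2 diet responses was 5.09-fold for Lyz2, 2.47-fold for C1qc, 2.47-fold for C1qb and 3.03-fold for Adgre1, with edgeR adjusted p of 0.0371, 0.0376, 0.0421 and 0.0472. Lyz2 went from 362 ± 27 (n = 3) to 237 ± 71.9 CPM (n = 4) in C57BL/6J and from 210 ± 41.1 to 700 ± 434 CPM (n = 4 each) in CAST/EiJ. These 4 calls were lost in 12, 13, 15 and 19 of 28 alternative fits, with adjusted p of up to 0.0944, 0.101, 0.111 and 0.103. The highest values were those without both libraries with the most oviduct RNA for Lyz2, without C57BL/6J 10% fat replicate 1 for C1qc and C1qb, and without C57BL/6J 44% fat replicate 1 for Adgre1. The log2 ratio of Adgre1 moved from 1.6 to 1 without C57BL/6J 10% fat replicate 2.

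Single genes of this interaction again included Acadm, whose ratio of responses was 1.53-fold, Dnajc15 at 2.94-fold, Unc93b1 at 2.32-fold, Fermt3 at 3.15-fold and Lipa at 2.58-fold, with an edgeR adjusted p of 0.0118 each. These 5 stayed past the threshold in the 28 alternative fits for single genes, with adjusted p of up to 0.0415; edgeR on these strains alone was not among the 28. Cyp4f14 (6.68-fold, 0.0118), the cathepsins Ctsa (1.66-fold, 0.0169) and Ctsz (1.76-fold, 0.0169), Tmem86a (2.94-fold, 0.0179) and the complement-like protease C1rl (3.92-fold, 0.0179) were also past it. Without C57BL/6J 10% fat replicate 1, Ctsa, Ctsz, Tmem86a and C1rl were lost, with an adjusted p of 0.0594 each. With 2 surrogate variables Cyp4f14 (0.0568) and C1rl (0.0652) were lost, and without both libraries with the most oviduct RNA Ctsa (0.0522), Ctsz (0.0526) and C1rl (0.0522).

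Of 16 steroidogenesis genes 0 passed in this interaction in edgeR and 5 responded more upward in CAST/EiJ adjusted over the list alone, with a camera adjusted p of 0.000274, or an adjusted p of 0.113 with an estimated correlation. Of 20 fatty acid oxidation genes, Acadm passed over all genes and 2 passed adjusted over the list alone, both more upward in CAST/EiJ; Acadvl had a ratio of 1.31-fold and an adjusted p of 0.0874 in edgeR and 0.0245 in DESeq2. The camera adjusted p of the list was 0.000274, or an adjusted p of 0.336 with an estimated correlation. Of 8 theca and interstitial cell markers 2 responded more downward in CAST/EiJ, over all genes and adjusted over the list alone. Camera gave an adjusted p of 0.0331, or an adjusted p of 0.644 with an estimated correlation and 0.0713 with the identifier series. The genes were Hhip and Ptch1, hedgehog pathway genes that bind the hedgehog ligand, with ratios 3.67 and 1.62 times lower and edgeR adjusted p of 0.0361 and 0.0472. Hhip was lost in 14 and Ptch1 in 20 of 28 alternative fits, with adjusted p of up to 0.12 and 0.167, both without C57BL/6J 10% fat replicate 1.

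For this interaction 124 genes passed in edgeR, 114 more upward and 10 more downward in CAST/EiJ. DESeq2 gave 851, 548 upward and 303 downward, which held all 124, and limma with library weights 1341. Leaving out 1 library moved the count to 865 and 8 without C57BL/6J 10% fat replicates 2 and 1, 58 without C57BL/6J 10% fat replicate 3, and 18, 19 and 30 without C57BL/6J 44% fat replicates 1, 2 and 3. It was 31 and 196 without CAST/EiJ 10% fat replicates 1 and 3, 69 and 57 without CAST/EiJ 44% fat replicates 1 and 2, 66, 253 and 75 without NZO/HlLtJ 10% fat replicates 1, 3 and 4, and 58, 62 and 61 without NZO/HlLtJ 44% fat replicates 1, 2 and 4. The count was 49 with the identifier series, 75 with 2 surrogate variables, 17 with only these strains, and 15 without both libraries with the most oviduct RNA.

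Between NZO/HlLtJ and CAST/EiJ, 3 genes passed in edgeR, each less upward in NZO/HlLtJ. They were Tbx3, the actin-binding protein Cotl1 and Tst, with ratios 2.62, 2.16 and 2.28 times lower and an adjusted p of 0.0432 each. Tbx3 went from 53.2 ± 9.54 to 117 ± 10.7 CPM in CAST/EiJ and from 146 ± 27.7 to 123 ± 10.9 CPM in NZO/HlLtJ (n = 4 each). Tmem86a and Dnajc15 followed with an adjusted p of 0.063 each, and 0.000107 and 0.000171 in DESeq2. Without NZO/HlLtJ 10% fat replicate 2 both passed (0.0411 and 0.0253), and Tmem86a without CAST/EiJ 44% fat replicate 4 (0.0428) and with 2 surrogate variables (0.0483). DESeq2 gave 194 genes, which held all 3, and limma with library weights 211. The 3 calls were lost in 15, 20 and 19 of 28 alternative fits, with adjusted p of up to 0.169, 0.212 and 0.212. The count was 10 without NZO/HlLtJ 10% fat replicate 2, 5 without CAST/EiJ 10% fat replicate 3, 1 without C57BL/6J 44% fat replicate 1 or 4, and 2, 3 or 4 in 5 fits, and 0 in the other 14. Those 14 left out C57BL/6J 10% fat replicate 2 or 3, C57BL/6J 44% fat replicate 2 or 3, CAST/EiJ 10% fat replicate 1 or 4, CAST/EiJ 44% fat replicate 1 or 3, NZO/HlLtJ 10% fat replicate 3 or 4, or any of the 4 NZO/HlLtJ 44% fat replicates. It was 0 with the identifier series or with only these strains, 10 with 2 surrogate variables and 5 without both libraries with the most oviduct RNA.

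The steroidogenesis, matrix and macrophage lists responded less upward in NZO/HlLtJ than in CAST/EiJ. In camera the adjusted p were 1.17e-06, 6.75e-10 and 1.49e-09 for the 3 lists, and the adjusted p were 0.00769, 0.243 and 0.243 with an estimated correlation. Of 16 steroidogenesis genes 0 passed in edgeR and 5 passed downward adjusted over the list alone, with Cyp11a1 at a ratio 2.88 times lower and Fdx1 2.25 times lower (adjusted p of 0.165 each). Of 23 matrix genes 0 passed and 9 did adjusted over the list alone, with Mmp2 2.52 times lower (0.165), and of 13 macrophage markers 0 passed and 10 did adjusted over the list alone, with C1qb 2.15 times lower (0.165). DESeq2 called these 4 genes, with adjusted p of 0.0119, 0.0136, 0.0117 and 0.0191.

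Between NZO/HlLtJ and C57BL/6J, 0 genes passed for a different diet response in edgeR, with 791 at an unadjusted p under 0.05, while DESeq2 gave 5 and limma with library weights 0. The unfolded protein response moved apart as a group. Camera gave an adjusted p of 7.59e-14, or an adjusted p of 0.147 with an estimated correlation. Of its 20 genes 0 passed over all genes and 7 responded more downward in NZO/HlLtJ adjusted over the list alone, among them Hspa5, with a ratio 1.82 times lower, and Hyou1, a further chaperone of the endoplasmic reticulum, 1.59 times lower (edgeR adjusted p of 1 each). Hspa5 went from 1130 ± 76 to 883 ± 95.4 CPM in NZO/HlLtJ (n = 4 each). The genes with the smallest p were the cyclin Ccnyl1 (adjusted p of 0.844 in edgeR and 0.00467 in DESeq2), Socs3 and Cish, feedback inhibitors of cytokine signalling, Hspa5 and the septin Sept5, with edgeR adjusted p of 1 for these 4.

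Across the 20189 genes, the diet effects of CAST/EiJ ran against those of C57BL/6J, with a Pearson r of -0.337 and a Spearman rho of -0.237. The pair C57BL/6J and NZO/HlLtJ had r = 0.19 and rho = 0.221, and CAST/EiJ and NZO/HlLtJ had r = -0.098 and rho = -0.162. Over genes with a mean of at least 5 CPM the r were -0.305, 0.388 and -0.188 in this order. These are correlations across genes, which are not independent replicates, and no test was made of them. Without CAST/EiJ 10% fat replicate 2 the r of C57BL/6J and CAST/EiJ was -0.047, and without NZO/HlLtJ 10% fat replicate 3 that of C57BL/6J and NZO/HlLtJ was 0.082. That of CAST/EiJ and NZO/HlLtJ was -0.06 without NZO/HlLtJ 44% fat replicate 3.

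Strain differences averaged over diets were far more numerous than diet effects. Ovaries of NZO/HlLtJ had more counts of oocyte genes than those of C57BL/6J and fewer of smooth muscle, macrophage and steroid synthesis genes. Camera adjusted p were 8.27e-05, 0.000147, 0.000179 and 0.0459 in this order, and the adjusted p were 0.673, 0.673, 0.673 and 0.654 with an estimated correlation. The steroidogenesis list was lost also without CAST/EiJ 10% fat replicate 2 (0.0684) and without both libraries with the most oviduct RNA (0.0908). Of 18 oocyte genes 8 were higher and 10 did not pass, and 10 were higher adjusted over the list alone. Nlrp5, a maternal factor stored in the egg, was 1.95-fold higher, at 37.6 ± 16.9 (n = 3) and 51 ± 5.97 CPM (n = 4) on 10% and 44% fat in C57BL/6J and 86 ± 16.3 and 84.6 ± 11.9 CPM (n = 4 each) in NZO/HlLtJ (edgeR adjusted p of 6e-04). The oocyte transcription factor Nobox was 1.84-fold higher (0.0024). Of 10 smooth muscle and pericyte genes 9 were lower, also adjusted over the list alone, with smooth muscle actin Acta2 1.73 times lower and myosin Myh11 1.74 times lower (0.000305 and 0.00205). Of 13 macrophage markers 9 were lower, also adjusted over the list alone, with Cd68 2.1 times lower (0.00023).

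Of 16 steroidogenesis genes 7 were lower in NZO/HlLtJ than in C57BL/6J, also adjusted over the list alone. Cyp11a1 was 3.67 times lower, at 5370 ± 1090 and 5160 ± 1030 CPM on 10% and 44% fat in C57BL/6J (n = 3 and 4) and 1520 ± 605 and 1350 ± 388 CPM in NZO/HlLtJ (n = 4 each), with an edgeR adjusted p of 6.39e-07, and Scarb1 was 1.97 times lower (0.000321). Fdx1, 1.37 times lower (0.0294), was lost in fits without C57BL/6J 10% fat replicate 1 or 3, C57BL/6J 44% fat replicate 1 or 3, NZO/HlLtJ 10% fat replicate 4 or NZO/HlLtJ 44% fat replicate 1 or 2, with adjusted p of 0.0673, 0.0551, 0.0617, 0.0596, 0.0547, 0.0532 and 0.0614 in this order. It was lost also with the identifier series (0.0697), 2 surrogate variables (0.185) and without both libraries with the most oviduct RNA (0.0521). Of 20 unfolded protein response genes 7 were lower, 9 adjusted over the list alone, with the degradation factor Edem1 1.45 times lower (1.64e-05). Camera gave this list an adjusted p of 0.00339, or an adjusted p of 0.673 with an estimated correlation.

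In all, 4828 genes differed between NZO/HlLtJ and C57BL/6J in edgeR, 2345 higher and 2483 lower in NZO/HlLtJ, and limma with library weights gave 7949. Among the largest increases were the somatostatin receptor Sstr1 (90.7-fold), the interferon-inducible genes Ifi202b (48-fold) and Gbp2b (33.2-fold), the melanocortin receptor partner Mrap2 (22.6-fold), the guidance cue Slit2 (15.3-fold) and Tnfsf11, the RANK ligand (14-fold). Those of the alpha globin Hba-a1, the histone Hist2h2aa2 and Tpm3-rs7, which has the name of a tropomyosin-related sequence, are uncertain because each has nearly identical copies. Obox2, an oocyte homeobox gene (chromosome 7, 15388721 to 15398545), had 0 counts in the 8 NZO/HlLtJ libraries and was at least 1490-fold lower, against a floor of 3 counts over those libraries. Mndal was 275 times lower, the zinc finger gene Zfp607 99.3 times, Paqr9 70.1 times, the catenin Ctnna2 23.3 times, the carbohydrate kinase Fggy 19.6 times, Islr2 17.5 times and Eps8l1 14.2 times. Apol7e and Oog1, at 4 counts each over the 8 NZO/HlLtJ libraries, belong to families of close paralogs, as does Obox2, and are uncertain. On the log2 scale, Mrap2 moved from 4.5 to 5.16 and Paqr9 from -6.13 to -5.45 without C57BL/6J 10% fat replicate 2, and Ifi202b from 5.58 to 6.18 without C57BL/6J 44% fat replicate 2. With 2 surrogate variables Tnfsf11 moved from 3.8 to 2.79, Islr2 from -4.13 to -3.37 and Paqr9 to -6.72.

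Ovaries of CAST/EiJ had fewer counts of interferon-stimulated, antigen presentation and lymphocyte genes than those of C57BL/6J. In camera the adjusted p were 0.000114, 0.00354 and 0.00424, and the adjusted p were 0.917, 0.882 and 0.882 with an estimated correlation. The interferon score was 0 in CAST/EiJ 44% fat replicate 1 and -1.92 to -1.64 in the other 3 libraries of its group. Of 21 interferon-stimulated genes 15 were lower and 2 higher, also adjusted over the list alone. The viral RNA sensor Ddx58 was 2.08 times lower and Oasl2 6.97 times lower, at 72 ± 28.4 and 67.9 ± 2.77 CPM in C57BL/6J (n = 3 and 4) and 12 ± 4.7 and 8.37 ± 6.25 CPM in CAST/EiJ (n = 4 each), while the antiviral GTPase Mx2 was 8.21-fold higher (edgeR adjusted p of 2.85e-09, 8.8e-08 and 7.35e-08). Of 8 genes of MHC class II 7 were lower and 1 higher, also adjusted over the list alone, with its master regulator Ciita 3.7 times lower and H2-Ab1 3.96 times lower (3.68e-07 and 1.47e-06). The higher gene was H2-Ea-ps, with 0 counts in C57BL/6J, and because of its fitted value the list's mean log2 fold change of 0.0507 differed in sign from its median of -1.65 and from its test. Of 8 markers of T and NK cells 7 were lower, also adjusted over the list alone, with the T cell receptor chain Cd3g 10.1 times lower, from under 2 CPM in every group (4e-08).

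Markers of white adipocytes and of theca cells were higher in CAST/EiJ than in C57BL/6J. In camera the adjusted p was 0.0348 for theca cells, or an adjusted p of 0.882 with an estimated correlation. The adipocyte list, which varied by library as given above, did not pass (0.0917), and passed with the identifier series as a term (0.0362). All 10 adipocyte markers were higher, also adjusted over the list alone, with the lipid droplet protein Plin1 2.93-fold higher (edgeR adjusted p of 8.22e-06) and the adipokine Cfd at 0.0659 ± 0.0624 and 7.05 ± 11.7 CPM in C57BL/6J (n = 3 and 4) and 112 ± 207 and 42.9 ± 56.9 CPM in CAST/EiJ (n = 4 each; 0.00422). Of 8 theca and interstitial cell markers 5 were higher and 1 lower, also adjusted over the list alone, with the theca hormone Insl3 11.3-fold higher and the hedgehog target Gli1 2.56-fold higher (4.25e-08 and 2.85e-06). Of 24 cholesterol genes 10 were lower and 1 higher, also adjusted over the list alone, with Hmgcs1, an early enzyme of the pathway, 2.3 times lower (0.00034). The camera adjusted p was 0.0348, or an adjusted p of 0.931 with an estimated correlation and 0.0605 with the identifier series. The log2 value of Insl3 moved from 3.49 to 4.08 without C57BL/6J 10% fat replicate 2. Cfd moved from 6.58 to 4.71 without CAST/EiJ 10% fat replicate 2, 5.91 without CAST/EiJ 44% fat replicate 1, 5.96 without both libraries with the most oviduct RNA and 7.82 without C57BL/6J 44% fat replicate 1.

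In all, 9451 genes differed between CAST/EiJ and C57BL/6J in edgeR, 4690 higher and 4761 lower in CAST/EiJ. Among the largest increases were Gsdma3, a gasdermin of skin (chromosome 11, 98626360 to 98638226), with 0 counts in the 7 C57BL/6J libraries and at least 3730-fold higher against a floor of 3 counts over them, Gad1, the enzyme that makes the transmitter GABA (566-fold), Tspan10 (370-fold), Cst9 (276-fold), the umami taste receptor gene Tas1r1 (156-fold) and AK157302 (333-fold). Eno1b, Amd2 and Tpm3-rs7 were higher too and are uncertain, since their sequences resemble those of other genes. Lower genes included Iigp1 (chromosome 18, 60376029 to 60392627) and Tgtp2, GTPases induced by interferon. Iigp1 and the prostaglandin F synthase Fam213b had 0 counts in the 8 CAST/EiJ libraries and were at least 2080-fold and 1630-fold lower. Tmem254b, with 2 counts there, had a ratio of 2480 (95% exact interval 685 to 20500) and, like Tgtp2, Trim30d, Apol7e and the carboxylesterase Ces2a, has close paralogs and is uncertain. The proton pump Atp12a and the meiotic cohesin Rec8 were 906 and 100 times lower. Of the 860 genes that passed and lay beyond 3 on the log2 scale, 388 higher and 472 lower, 18.1% were pseudogenes, as against 3.84% of all genes tested. In log2 fold change, Gad1 moved from 9.14 to 10.1 without C57BL/6J 10% fat replicate 2, AK157302 from 8.38 to 9.1 without C57BL/6J 10% fat replicate 3 and 9.78 without C57BL/6J 44% fat replicate 3, Tmem254b from -11.12 to -12.32 without CAST/EiJ 44% fat replicate 2, and Cst9 from 8.11 to 8.88 with 2 surrogate variables.

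The mitochondrial gene mt-Co2, subunit 2 of cytochrome c oxidase, stood at 1730 ± 189 and 1570 ± 165 CPM in C57BL/6J (n = 3 and 4) and at 4.87 ± 1.56 and 6.03 ± 1.71 CPM in CAST/EiJ (n = 4 each), 303 times lower (edgeR adjusted p of 1.69e-18). It shares sequence with the nuclear pseudogene Gm13341 (chromosome 2, 22587291 to 22587962), which averaged 0.0703 CPM in C57BL/6J and 1100 CPM in CAST/EiJ, and its value is uncertain.

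Ovaries of NZO/HlLtJ had more counts of interferon, antigen presentation and lymphocyte genes than those of CAST/EiJ, and fewer of the unfolded protein response. In camera the adjusted p were 0.000343, 0.00108, 0.00178 and 0.000161 in this order, and each list had an adjusted p of 0.828 with an estimated correlation. Of 21 interferon-stimulated genes 11 were higher and 1 lower, also adjusted over the list alone, with Oasl2 5.42-fold higher (edgeR adjusted p of 3.59e-07). The lower gene was Mx2, at 0.0471 ± 0.0423 and 0.0589 ± 0.0245 CPM in NZO/HlLtJ and 34.8 ± 9.48 and 37.4 ± 31.5 CPM in CAST/EiJ (n = 4 each; 6.87e-13). Of 8 MHC class II genes 7 were higher, also adjusted over the list alone, with H2-Eb1 3.55-fold higher (1.43e-06), and of 8 markers of T and NK cells 7 were higher, also adjusted over the list alone, with the NK cell receptor Ncr1 16.5-fold higher (1.78e-07). Of 20 unfolded protein response genes 16 were lower, also adjusted over the list alone, with Hyou1 1.6 times and Pdia6 1.68 times lower (2.87e-06 and 1.64e-06). Of 10 adipocyte markers 8 were lower, 9 adjusted over the list alone, with the fatty acid carrier Fabp4 20 times lower (0.00117), and the list did not pass in camera (0.247). On the log2 scale, Fabp4 moved from -4.32 to -2.6 without CAST/EiJ 10% fat replicate 2 or both libraries with the most oviduct RNA and -4.96 without NZO/HlLtJ 44% fat replicate 3, and Ncr1 from 4.05 to 5.13 without CAST/EiJ 44% fat replicate 1.

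In all, 9714 genes differed between NZO/HlLtJ and CAST/EiJ in edgeR, 4717 higher and 4997 lower in NZO/HlLtJ. The largest differences again included Iigp1, at least 2370-fold higher in NZO/HlLtJ, Fam213b, at least 808-fold higher, and Sstr1 (195-fold). Nlrp1a, a sensor of the inflammasome, and Obox2 had 0 counts in NZO/HlLtJ and were at least 538-fold and 541-fold lower. AK157302, with 1 count over the 8 NZO/HlLtJ libraries, had a ratio of 4380 (95% exact interval 785 to 173000). Gsdma3, Cst9, Gad1, Tspan10 and Mndal were 1140, 867, 289, 194 and 190 times lower. Copies of Plac9b, Tmem254b, Tgtp2, Hist2h2aa2, Hba-a1 and Eno1b make their values uncertain. The log2 value of Cst9 moved from -9.76 to -10.86 without NZO/HlLtJ 10% fat replicate 2 and -11.73 without NZO/HlLtJ 44% fat replicate 4, and that of AK157302 from -11.32 to -12.06 without NZO/HlLtJ 10% fat replicate 1.

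Genes chosen for known strain alleles differed in part. Nnt, the transhydrogenase of mitochondria that carries a deletion in C57BL/6J, was 2.03-fold higher in CAST/EiJ and 1.58-fold higher in NZO/HlLtJ than in C57BL/6J (edgeR adjusted p of 3.48e-08 and 3.09e-05) and 1.28 times lower in NZO/HlLtJ than in CAST/EiJ (0.00272). H2-Ea-ps, a class II gene silent in C57BL/6J, had 0 counts there and was at 6.6 ± 2.52 and 8.27 ± 4.25 CPM in CAST/EiJ and 21.3 ± 6.31 and 26.2 ± 6.45 CPM in NZO/HlLtJ (n = 4 each). The antiviral gene Mx1 was 4.6-fold higher in CAST/EiJ and 6.97-fold higher in NZO/HlLtJ than in C57BL/6J (0.00105 and 0.000368), and its log2 value in CAST/EiJ moved from 2.2 to 1.58 without CAST/EiJ 44% fat replicate 1. Ifi202b was 48-fold higher in NZO/HlLtJ than in C57BL/6J (5.64e-09), and 1.21-fold in CAST/EiJ (0.613), which passed without C57BL/6J 44% fat replicate 2 at a log2 fold change of 0.87; without it the value of NZO/HlLtJ moved from 5.58 to 6.18. Zfp69, a zinc finger gene tied to diabetes in obese strains, was 1.46-fold higher in CAST/EiJ than in C57BL/6J (0.00765), while its ratio of 1.16-fold between NZO/HlLtJ and C57BL/6J did not pass (0.357). Of the 5 genes 4 were higher in NZO/HlLtJ and 4 in CAST/EiJ than in C57BL/6J, also adjusted over the list alone. Camera adjusted p were 8.27e-05 and 0.0348, and the adjusted p were 0.0865 and 0.882 with an estimated correlation; between NZO/HlLtJ and CAST/EiJ, where 2 were higher and 1 lower (2 and 2 adjusted over the list alone), it was 0.428.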

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

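Each test of an explanation below was chosen only after the result was seen, while the counts of other splits of the libraries were set by the procedure. A library was taken as far from the others when its gap to the nearest of its group of 4, as a share of the group's range, exceeded the 95% critical value of Dixon's test. Chance gives about 1 in 20 groups such a library, or 17.8 of the 355 tested. There were 47, of which 16 fell in CAST/EiJ 10% fat replicate 2. They made up 4 of 35 groups for library measures, 11 of 170 for list scores and 32 of 150 for single genes, against 1.75, 8.5 and 7.5 by chance.

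Among library measures, NZO/HlLtJ 44% fat replicate 4 held 43.54 M counts (others 31.94 to 33.75) and 2.909% mitochondrial counts (3.638 to 3.683). CAST/EiJ 10% fat replicate 2 held 1.272% pseudogene counts (1.424 to 1.441) and had a scaling factor of 0.9703 (0.9974 to 0.9991). Among list scores, the same library stood apart for granulosa cells (-1.18, others 0.35 to 0.45), oviduct epithelium (6.37, others 0 to 0.46), the ovulatory response (2.97, others -0.2 to 0.33) and fatty acid synthesis (0.93, others -0.02 to 0.1). The ovulatory response also stood apart in CAST/EiJ 44% fat replicate 4 (0.33, others -0.06 to -0.02) and NZO/HlLtJ 10% fat replicate 3 (0.87, others -0.14 to 0.01). Further scores far from their group were luteal cells in NZO/HlLtJ 44% fat replicate 3 (-0.44, others 0.12 to 0.17) and insulin and IGF signalling in NZO/HlLtJ 44% fat replicate 1 (0.08, others -0.01 to 0). In CAST/EiJ on 44% fat they were hypoxia and glycolysis in replicate 3 (0.27, others -0.01 to 0.01), and in replicate 1 interferon-stimulated genes (0, others -1.92 to -1.64) and extracellular matrix (0.39, others 0 to 0.05).

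Among single genes, CAST/EiJ 10% fat replicate 2 stood apart with 4780 CPM of Ovgp1 (others 0.54 to 4.07), 109 of Foxj1 (0.352 to 1.51), 198 of Adipoq (0.946 to 6.52), 126 of Plin1 (51.4 to 58.9) and 752 of Fabp4 (10.9 to 30.1). It also had 13 CPM of Pappa2 (0.968 to 1.74), 16.4 of Ptgs2 (0.117 to 1.19), 86.3 of Nnt (123 to 125), 0.244 of Ifi202b (0.496 to 0.516) and 14.1 of Lep (0.124 to 0.633). C57BL/6J 44% fat replicate 1 had 22.2 CPM of Foxj1 (0.0845 to 2.54), 13 of Adipoq (0.0277 to 1.38), 35.1 of Fabp4 (5.8 to 10.4) and 1.07 of Lep (0 to 0.176). In the same group replicate 4 had 0.101 CPM of S100a9 (0.579 to 0.592), replicate 3 had 1.85 of Zfp69 (2.9 to 2.92) and replicate 2 had 1.78 of Ifi202b (0.194 to 0.402). CAST/EiJ 10% fat replicate 3 had 408 CPM of Lhcgr (129 to 146). On 44% fat, CAST/EiJ replicate 3 had 21.1 CPM of Ovgp1 (2.01 to 4.04) and 41.2 of Plin1 (97.1 to 99.8), replicate 1 had 1.24 of Foxj1 (0.649 to 0.729) and 17.3 of Mx1 (2.08 to 3.35), and replicate 2 had 1170 of Lhcgr (290 to 386) and 82.3 of C1qb (42.9 to 47.1). NZO/HlLtJ 10% fat replicate 3 had 10.5 CPM of Fabp4 (1.76 to 3.14), 29.6 of Pappa2 (0.458 to 1.42) and 14 of Dmbt1 (0.115 to 0.549). Replicate 4 of that group had 31.9 CPM of Plin1 (43.1 to 45), 1.13 of S100a8 (0.13 to 0.298), 2.41 of S100a9 (0.229 to 0.543) and 0.157 of Lep (0 to 0.0229), and NZO/HlLtJ 44% fat replicate 3 had 2.95 of Adipoq (0.0606 to 0.375).

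Interaction terms of strain and diet passed in edgeR for 23 genes over all strains, 124 for CAST/EiJ against C57BL/6J and 3 for NZO/HlLtJ against CAST/EiJ. Over all strains the adjusted p was 0.02 for each of Tbx3, Dnajc15, Acadm, Fermt3, Cyp4f14, Tmem86a, Tst, Unc93b1, Lipa and Ctsa. For CAST/EiJ against C57BL/6J the log2 differences were 0.61 for Acadm, 1.56 for Dnajc15, 1.21 for Unc93b1, 1.65 for Fermt3, 1.37 for Lipa, 2.74 for Cyp4f14, 0.73 for Ctsa, 0.81 for Ctsz, 1.56 for Tmem86a and 1.97 for C1rl. For NZO/HlLtJ against CAST/EiJ they were -1.39 for Tbx3, -1.11 for Cotl1 and -1.19 for Tst. Of the gene lists, 8 passed for NZO/HlLtJ against C57BL/6J (0 with an estimated correlation), 9 for CAST/EiJ against C57BL/6J (0) and 11 for NZO/HlLtJ against CAST/EiJ (1).

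Other splits of the libraries into groups of the same sizes gave as many genes as the real labels in 2 of 35 splits for diet in CAST/EiJ, so chance cannot be excluded (real 126, highest other 196, from exchanging CAST/EiJ 44% fat replicate 1 and CAST/EiJ 10% fat replicate 2). Where the real count was 0, every split gives as many by construction, so that the splits do not test chance, which cannot be excluded, for diet in C57BL/6J (35 of 35 splits, highest other 105), in NZO/HlLtJ (35 of 35, highest other 1), averaged over strains (100 of 100, highest other 618) or the interaction of NZO/HlLtJ against C57BL/6J (100 of 100, highest other 80). Few splits gave as many genes for the interaction over all strains (2 of 100, real 23, highest other 112), CAST/EiJ against C57BL/6J (2 of 100, real 124, highest other 392) and NZO/HlLtJ against CAST/EiJ (3 of 100, real 3, highest other 43). The splits with 105, 618 and 80 genes, where the real labels gave 0, point to a structure of the samples. So do the 112, 392 and 43 genes, several times the real counts from 1 split, and chance is not excluded for these interactions. That split exchanged the diet labels of 6 of the 8 CAST/EiJ libraries, all but CAST/EiJ 44% fat replicate 1 and CAST/EiJ 10% fat replicate 2. Its CAST/EiJ groups were thus those of the split with 196 genes, mirrored. Chance was excluded for the strain differences, where only the real labels, 1 of 100 splits, gave as many genes. These were NZO/HlLtJ against C57BL/6J (real 4828, highest other 1824), CAST/EiJ against C57BL/6J (9451, highest other 4102) and NZO/HlLtJ against CAST/EiJ (9714, highest other 1476).

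The first pattern was the diet response of CAST/EiJ, with 126 genes past the threshold and a median log2 fold change of 1.01 (SE 0.24) over 13 macrophage markers, 7 of them past it. Without CAST/EiJ 10% fat replicate 2, 121 genes passed, 69 of them among the 126, which argues against oviduct and fat RNA in that library as the whole cause. Of 4 list scores tried as a term, the adipocyte score, which 380 genes followed, left 98 genes. With it the macrophage median was 1.01 (median SE of single markers 0.23, 6 past), and these values argue against attached fat. The oviduct score left 88 genes. With the luteal score 4 genes passed and the macrophage median was 1.18 (SE 0.33, 0 past), but this score separated the diets without overlap (-1.48 to -0.53 on 10% fat, -0.12 to 0.14 on 44% fat), so more luteal tissue and a diet effect cannot be told apart; the macrophage score left 1 gene. An effect of diet on the ovary and a difference in cycle stage between the groups both stay open, and the limit of 1.5 times for a loss of genes was set after these counts were seen.

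The second pattern was mt-Co2, at 1640 CPM in C57BL/6J, 5.45 in CAST/EiJ and 1480 in NZO/HlLtJ. The nuclear pseudogene Gm13341, found by a search for pseudogenes higher in CAST/EiJ, had 0.0703, 1100 and 0.431 CPM, and 54% of its 25-base words occur in mt-Co2. Summed over both, the log2 ratio of CAST/EiJ to C57BL/6J was -0.57, within the range of the 12 other mitochondrial mRNAs (-0.85 to 0.79) and far from the -8.23 of mt-Co2 alone, which argues against lower expression of mt-Co2. Reads of CAST/EiJ mt-Co2 counted on the nuclear copy are a candidate explanation, and which bases of CAST/EiJ draw them there was not tested.

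The third pattern was the set of 860 genes past the threshold and beyond 3 on the log2 scale between CAST/EiJ and C57BL/6J. Pseudogenes made up 18.1% of them against 3.84% of all genes tested (odds ratio 6.69, Fisher exact p of 7.79e-63), with the limit of 3 chosen after the data were seen. Reads moved between nearly identical gene copies may explain part of this set. True strain differences in gene content or expression, and in how well reads match GRCm38, stay open, as untested.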

How the results depend on the processing

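Of the settings below, the fit without both libraries with the most oviduct RNA (CAST/EiJ 10% fat replicate 2 and C57BL/6J 44% fat replicate 1), the correlations with each library left out and the gene list tests without 1 or both of these libraries were added after the results were seen. No paired analysis was possible because the labels give no number that links libraries between groups. Counts of genes that differed between strains stayed within 1.5 times under each alternative, except for NZO/HlLtJ against C57BL/6J in limma with library weights, with 7949 genes that held 4734 of the 4828. Under relative log expression scaling, and with no filter on low counts, each of the 11 counts of genes stayed within 1.5 times. Counting error was small beside the spread between libraries, so depth limited the calls less than that spread did.

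In edgeR, 0 genes passed for diet in C57BL/6J, in NZO/HlLtJ and averaged over strains and for the interaction of NZO/HlLtJ against C57BL/6J, with 1783, 710, 1190 and 791 at an unadjusted p under 0.05. DESeq2 called 70, 4, 18 and 5 genes there, and limma with library weights called 832, 2, 1 and 0. For diet in CAST/EiJ (126 genes), DESeq2 called 596 that held 124 of them, limma with library weights 240 (96), limma on the variance-stabilised values 80 (75) and edgeR with the identifier series 66 (65). For the interaction over all strains (23 genes), DESeq2 called 544 and limma with library weights 998, each with all 23, edgeR with the identifier series 2 (2), and edgeR with 2 surrogate variables 3 (0 of the 23). For CAST/EiJ against C57BL/6J (124 genes), DESeq2 called 851 (124), limma with library weights 1341 (120), edgeR with the identifier series 49 (47) and with 2 surrogate variables 75 (39). For NZO/HlLtJ against CAST/EiJ (3 genes), DESeq2 called 194, limma with library weights 211 and edgeR with 2 surrogate variables 10, each with all 3, and edgeR with the identifier series 0 (2033 unadjusted).

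With only the groups compared, edgeR called 0 genes for diet in CAST/EiJ (1926 unadjusted), 17 for CAST/EiJ against C57BL/6J (13 of the 124) and 0 for NZO/HlLtJ against CAST/EiJ (2265 unadjusted), where fewer libraries estimate the spread. Without both libraries with the most oviduct RNA, edgeR called 0 for the interaction over all strains (3003 unadjusted), 15 for CAST/EiJ against C57BL/6J (13 of the 124) and 5 for NZO/HlLtJ against CAST/EiJ (all 3). The cause of these changes was not tested.

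With each library left out in turn, edgeR called 0 to 326 genes for diet in C57BL/6J, 28 to 221 in CAST/EiJ, 0 to 1 in NZO/HlLtJ and 0 to 7 averaged over strains. The interactions gave 0 to 320 genes over all strains, 0 to 0 for NZO/HlLtJ against C57BL/6J, 8 to 865 for CAST/EiJ against C57BL/6J and 0 to 10 for NZO/HlLtJ against CAST/EiJ. Leaving out C57BL/6J 10% fat replicate 2 gave the 326, 7, 320 and 865, and leaving out CAST/EiJ 44% fat replicate 2 gave the 28. Strain counts ranged over 3503 to 5594, 8464 to 10021 and 9046 to 9933. Correlations of diet effects ranged from -0.354 to -0.047 between C57BL/6J and CAST/EiJ, 0.082 to 0.273 between C57BL/6J and NZO/HlLtJ, and -0.122 to -0.06 between CAST/EiJ and NZO/HlLtJ. At a mean of at least 5 CPM the last 2 were 0.388 and -0.188.

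Of the 91 list tests past the threshold, 2 passed with an estimated correlation, and 105 list tests passed without CAST/EiJ 10% fat replicate 2. Of 94 list results checked, 89 were lost with an estimated correlation, 0 changed with relative log expression scaling, 15 were lost and 1 gained with the identifier series, 13 were lost without both libraries and 6 without CAST/EiJ 10% fat replicate 2. The ovulatory list for diet in CAST/EiJ reversed without both libraries (camera adjusted p of 0.99) and without CAST/EiJ 10% fat replicate 2 (0.98), in a range of 0.000135 to 0.99 over its alternatives. Tnfaip6 for diet in CAST/EiJ reversed from -2.84 to 0.11 on the log2 scale in the same 2 fits, with adjusted p of 0.943 and 0.946. With each library left out it ranged from -3.32 to 0.11, and its adjusted p over all alternatives had a range of 0.0174 to 0.946. Among named genes, 182 results were past the threshold and 106 were not. DESeq2 lost 0 of 181 and gained 39 of 105, and it gave no value for Calb1 for diet in CAST/EiJ and for Foxj1 for diet in C57BL/6J. Relative log expression scaling changed 0, the identifier series lost 24, 2 surrogate variables lost 29 and gained 2, and the fit without both libraries lost 28, gained 2 and reversed Tnfaip6. Leaving out single libraries lost 41 of the 182 in at least 1 fit.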

Other observations

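The lists given here were chosen after their tests were seen, and in each of them 0 genes passed in edgeR over all genes. Each passed in camera and was lost with an estimated correlation, whose adjusted p was the highest over its alternatives and is given second. On 44% fat in C57BL/6J, the list of 16 genes of hypoxia and glycolysis was lower, with 3 genes past adjusted over the list alone (adjusted p of 0.00351 and 0.596). It was lower in NZO/HlLtJ, with 0 past over the list alone (0.000933 and 0.376), and lost there also with the identifier series (0.117). In CAST/EiJ, the list of 24 genes of cholesterol synthesis and uptake was higher, with 1 past over the list alone (0.000311 and 0.948). Those of 16 genes of oxidative phosphorylation, with 1 past over the list alone (1.9e-05 and 0.547), and of 10 endothelial markers, with 0 past (0.00525 and 0.948), were higher too.

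By library, Pappa2 stood at 34.1, 0.859 and 29.5 CPM in C57BL/6J 10% fat replicates 1, 2 and 3, at 13 in CAST/EiJ 10% fat replicate 2 and at 29.6 in NZO/HlLtJ 10% fat replicate 3, and at 1.74 or less in the other libraries. Cyp17a1 stood at 4.69, 323 and 1.62 CPM in the same C57BL/6J libraries, at 38 in CAST/EiJ 10% fat replicate 2, 55.5 in CAST/EiJ 44% fat replicate 3 and 18 in NZO/HlLtJ 10% fat replicate 3, and at 165 or more in the other libraries.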
